A study of Arabidopsis thaliana with 4 samples.

How the data were processed

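Gene expression was measured on 4 Affymetrix arrays, 1 per genotype, in shoot apices carrying leaf primordia from Arabidopsis thaliana plants of the Col-0 background. Per the labels' protocols, plants were grown on soil for 14 days with 16 hours of light and 8 hours of dark, RNA was extracted with an RNeasy kit, and biotin-labelled cRNA was prepared by the standard protocol of the array's maker. The genotypes were wild type, the as1-1 mutant, the as2-1 mutant and an AS2 overexpressing line, and each array was placed in its group from its genotype label. Some of the free text attached to the samples speaks of embryos, which does not match the growth and tissue labels, and the latter were followed.

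The deposited values were a linear signal intensity for each probe set. The software and settings that produced them were not given in the sources used here. The mean signal after dropping the top and bottom 2% of probe sets was 198.4, 198.5, 198.4 and 198.5 on the wild type, as1-1, as2-1 and AS2 overexpressing arrays, as after scaling of whole arrays to a common level. The median signals were 82.5, 82.2, 80.7 and 75.7. Values ran up to 17878.2, and no detection call or error per probe set was used here. The table held 22746 probe sets and 0 control probe sets, so the planned check of RNA quality on the array's own controls was not run.

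Signals were put on the log2 scale and each array was centred on its median over the probe sets at or above the median mean level. Values under the 40th percentile of all scaled values, a signal of 42.9, were then raised to that floor. A signal of 0 was set to 0.1 where no floor was used. Where 1 array of a pair lay at the floor the difference was taken as a lower bound, counted and not ranked, and where both did no difference was computed. Of the 22746 probe sets, 13513 were listed with 1 gene, 503 with several and 8730 with none in the naming table, which follows a platform annotation that can be old. Symbols were updated through the RefSeq gene table of assembly TAIR10.1, where 13436 probe sets matched a locus. The array build was not given in the sources used here, so no coordinates are printed and that assembly served for names, for sorting genes into the nuclear and plastid genomes and for which genes lie near each other. The probe set with the highest mean level stood for each of the 147 genes with several, which left 13355 genes.

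With 1 array per genotype there was no replicate, so no test was run and no p-value or error between arrays exists. A gene was called higher or lower when its floored log2 difference was at least 1 in size, which is 2-fold. The number of arrays limits the precision of every value. The 5 comparisons were each mutant and the overexpressing line against wild type, as1-1 against as2-1, and the AS2 overexpressing line against as2-1. The genes to be named were fixed by a rule before the data were examined. The rule took, in each comparison with wild type, the 12 genes with the largest difference in each direction among called genes above the floor on both arrays, and any called member of a fixed list. It took the 8 genes per direction with the largest mean difference among those called in both mutants, and up to 8 per direction among those called in opposite directions in as2-1 and in the AS2 overexpressing line. AS1, AS2 and the class I KNOX genes were also to be named whatever their value, but no probe set carried these names in the table used here, so the check of each mutated gene on its own array could not be made and these genes were not analysed here.

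Gene lists, 29 in all with 257 genes, were fixed before the data were examined, and 35 of these genes were named on the array, in 18 lists. For lists with at least 3 measured members, the median log2 difference was set among the medians of 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays only. Another 3 lists were drawn up after values had been seen.

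Comparisons with the same wild type array share its chance values. Unchanged arrays were therefore simulated in 100 sets around each gene's mean level. Their spread was taken per level bin from the difference between the as1-1 and as2-1 arrays. Calls, overlaps and correlations were computed from them in the same way. The as1-1 and as2-1 arrays were the closest pair, with a robust spread of log2 differences of 0.265, against 0.338 to 0.388 for the other pairs. The noise was also drawn from a normal distribution with the spread of the middle of the differences, which leaves out rarer large ones. Simulated comparisons gave 19.2 genes at least 2-fold apart on average, where the as1-1 and as2-1 pair itself gave 55. The simulated counts and covariances may therefore be too low on both grounds. The calling steps were tested on simulated data for as1-1 against wild type, run on 13355 genes of which 200 were changed. Of genes simulated with log2 changes of 1.5, -1.5, 3.0 and -3.0, 98%, 94%, 100% and 100% were called, and 0.114% of unchanged genes were. The changed genes were drawn from those more than 2-fold above the floor, so these shares do not hold near it. The unchanged genes included those below the floor on both arrays, for which no difference is computed. The noise was drawn in the same normal way from the as1-1 and as2-1 pair, so the share of unchanged genes called may be too low.

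Alternatives were no centring, centring on all probe sets, quantile normalization, loess per pair of arrays (span 0.4, 3 iterations), a floor at the 25th or 60th percentile or none, size rules of 1.5-fold and 3-fold, the mean of a gene's probe sets, leaving out probe sets of the s and x types, and random lists not matched on level. Counting every probe set by itself and using the AS2 overexpressing array as reference in place of wild type were added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.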

Results

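AS1, a MYB-domain protein, and AS2, a plant-specific nuclear protein of the LBD family, act together in leaf primordia, and the series asked which genes depend on them. Transcript levels were compared among shoot apices of wild type, as1-1, as2-1 and AS2 overexpressing plants, with 1 array for each. No value below has a replicate, so every difference describes these 4 arrays and carries no error. Between 59.33% and 61.17% of the 22746 probe sets lay above the floor on each array, and 6819 named genes did so on all 4. Over these genes the as1-1 and as2-1 arrays were the closest pair (Pearson's r = 0.9758 across genes). Wild type stood at r = 0.9527 from as1-1, 0.95 from as2-1 and 0.9634 from the AS2 overexpressing array. Named reference genes used for normalization in plant work differed by less than 2-fold in each comparison with wild type, with list medians on the log2 scale of 0.0219 in as1-1, 0.0741 in as2-1 and 0.2 in the AS2 overexpressing array over 5 genes.

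The first comparison asked what differed when AS1 was mutated. COR27, a cold-regulated gene linked to the circadian clock, had a signal of 135.6 in wild type and 935.7 in as1-1, 6.9-fold higher. AT4G33980 was 5.18-fold higher and AT1G07050, of the CCT motif family, 4.38-fold higher in as1-1, and AT1G06830, a glutaredoxin family gene, went from 44.31 in wild type to 170 in as1-1. On the lower side stood AT1G59740, a nitrate and peptide transporter family gene (4.16-fold lower), AT3G01060 (3.98-fold lower), AT5G48490, a lipid transfer protein family gene (3.83-fold lower, from 2355 to 615), and AT5G59130 (3.71-fold lower). YAB5, a YABBY transcription factor gene of the abaxial side of the leaf, was 2.27-fold higher, at 344.4 against 151.5.

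Further genes among the largest differences in as1-1 were AT1G67865 (3.68-fold higher), AT1G62480 (3.67-fold higher), AT1G27030 (3.57-fold higher), AT5G22310 (3.52-fold higher), AT5G50335 (3.38-fold higher), AT4G19200 (3.24-fold higher), AT2G32220 (3.21-fold higher) and AT3G21480 (3.04-fold higher). Those lower in as1-1 were AT5G35970 (3.44-fold), AT1G73480 (3.23-fold), AT2G29670 (3.07-fold), the thionin gene AT1G66100 (2.84-fold), AT5G57345 (2.84-fold), AT5G56100 (2.81-fold), AT5G16030 (2.77-fold) and AT1G48100 (2.75-fold). Both named members of the cold and drought list were higher in as1-1, COR15A 3-fold, from 398.6 to 1195, and COR47, a dehydrin gene, 2.34-fold, from 1279 to 2990. AGL24, a MADS-box gene that promotes flowering, was the 1 named member of the floral list and was 2.06-fold lower, just under 2-fold with centring on all probe sets and at a log2 difference of -0.27 with the floor at the 60th percentile. None of the 4 named auxin response genes reached 2-fold, and their median log2 difference of 0.379 lay at percentile 97.6 of random lists matched on level and 97.2 of unmatched ones. WES1, IAA29 and IAA30 were higher and GH3.3 lower (-0.374). IAA29 and IAA30 lay near the floor in wild type, at 54.43 and 50.69. The reference gene AT5G15710 differed by more than any of them, at 0.647. In all, 222 of 7744 genes differed at least 2-fold, 110 higher and 112 lower in as1-1, and 38 of these were lower bounds. A simulated unchanged comparison gave 19.2 on average. Its spread came from as1-1 and as2-1, the closest pair, which itself gave 55 genes, so 19.2 may be too low. The balance turned to 125 higher and 87 lower with centring on all probe sets and 132 and 93 with loess, and the count was 97 with the floor at the 60th percentile, where AT1G59740 (log2 difference -0.532), AT5G59130 (-0.313), AT1G06830 (0.404), AT1G62790, AT5G22310, AT2G32220, AT3G21480, AT1G66100, AT5G56100 and AT1G48100 also fell under 2-fold, and 660 (201 higher and 459 lower) with it at the 25th. With the AS2 overexpressing array as reference in place of wild type, an alternative added after the data were examined, 223 genes differed, 148 higher and 75 lower, of which 71 were shared with the 222.

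The second comparison asked the same of AS2. Among probe sets with 1 named gene, the largest measured difference on the lower side was AT3G28220, 5.94-fold lower in as2-1, followed by AT1G73480 (5.81-fold lower) and LHCB4.2, which encodes a minor antenna protein of photosystem II, at 9332 in wild type and 1709 in as2-1 (5.46-fold lower). AT2G29670 was 4.98-fold lower, AT3G49160, of the pyruvate kinase family, 4.85-fold lower and GI, a clock and flowering time gene and the 1 named member of the evening list, 3.35-fold lower. AT3G22240 was 5.23-fold higher, COR27 4.94-fold higher and AT1G62790 4.13-fold higher in as2-1. YAB5 was 2.51-fold higher, at 380.2.

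Other genes higher in as2-1 were AT1G04770 (3.67-fold), scpl35, a serine carboxypeptidase-like gene (3.43-fold), the peroxidase gene AT5G64110 (3.22-fold), AT1G06830 (3.14-fold), AT1G07050 (3.12-fold), AT4G33980 (3-fold), AT3G09440, of the Hsp70 family (3-fold, from 584.1 to 1753), the calmodulin-like gene AT2G41090 (2.97-fold) and AT2G19310 (2.9-fold). DFR, an enzyme gene of anthocyanin synthesis, lay below the floor in wild type and at 132.5 in as2-1, at least 3.09-fold higher. Other genes lower in as2-1 were AT5G35970 (4.44-fold), AT3G01060 (4.43-fold), AT5G48490 (4.09-fold), the kinesin gene AT2G36200 (4.04-fold), AT5G56100 (3.93-fold) and TRXF2, a chloroplast thioredoxin gene (3.19-fold). Both named members of the fixed photosynthesis list stayed under 2-fold in both mutants, with RCA (Rubisco activase) at log2 differences of -0.925 in as1-1 and -0.745 in as2-1 and LHCB4.1 at -0.408 and -0.55. The 20 nuclear genes named for plastids or photosynthesis, a list drawn up after the data were examined that includes LHCB4.2, had median log2 differences of -0.48 in as1-1 and -0.485 in as2-1, and of -0.254 and -0.353 after quantile normalization. The auxin response list had a median log2 difference of -0.121 in as2-1. Of 7751 genes, 254 differed at least 2-fold, 116 higher and 138 lower, and 35 were lower bounds. Centring on all probe sets turned this balance to 137 higher and 107 lower and loess to 138 and 110, and the count was 116 with the floor at the 60th percentile, where AT1G04770, AT1G06830, AT4G33980, AT2G19310, AT2G32220, AT3G49160, AT5G56100, AT5G59130 and DFR fell under 2-fold, and 729 (219 higher and 510 lower) with it at the 25th. With the AS2 overexpressing array as the reference, 212 genes differed, 133 higher and 79 lower, of which 76 were shared with the 254.

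The mutants were then compared for genes that differed in both. Higher in both, by the mean of the 2 log2 differences, were COR27 (5.84-fold), AT4G33980 (3.94-fold), AT1G07050 (3.7-fold), AT1G06830 (3.47-fold), AT1G62790 (3.46-fold), AT1G62480 (3.17-fold), scpl35 (3.14-fold) and AT2G32220 (2.98-fold). Lower in both were AT1G73480 (4.33-fold), AT3G01060 (4.2-fold), AT5G48490 (3.96-fold), AT5G35970 (3.91-fold), AT2G29670 (3.91-fold), LHCB4.2 (3.8-fold), AT3G28220 (3.68-fold) and AT5G59130 (3.33-fold). Many of these genes also differed at least 2-fold from wild type, in the same direction, on the AS2 overexpressing array. These were COR27 (940.3 there), AT4G33980, AT1G07050, scpl35 and AT2G32220, higher, and AT1G73480 (110.9), AT3G01060 and AT5G35970, lower. In the same direction but under 2-fold there were AT1G62790 (log2 difference 0.986), AT1G62480 (0.871), AT5G48490 (-0.953), AT3G28220 (-0.876), LHCB4.2 (-0.65) and AT2G29670 (-0.418). AT1G06830 at 40.35 and AT5G59130 at 137.9 stayed near wild type.

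Of the genes measured in both comparisons, 55 were higher in both mutants, 69 lower in both and 0 in opposite directions, a balance that turned to 62 higher and 53 lower with centring on all probe sets and 64 and 58 with loess and moved to 107 higher and 306 lower with the floor at the 25th percentile. Independent lists would share 1.66 higher and 2.02 lower genes, and simulated unchanged arrays that shared 1 control gave means of 0.09 and 7.08. The simulated spread came from the closest pair of arrays and its normal noise leaves out rarer large differences. These means and the simulated covariance may therefore be too low. Across the 6819 genes above the floor on all arrays, the differences of as1-1 and as2-1 from wild type had r = 0.752 (Spearman's rho 0.729) and a covariance of 0.137, where unchanged arrays gave r = 0.5 and a covariance of 0.037. The wild type array is shared and single, so part of the excess may come from it. A pair of differences that share no array, as1-1 minus wild type and as2-1 minus AS2 overexpressing, had r = 0.386 (rho 0.366), where chance gives 0; genes are not independent replicates. The other pairings without a shared array gave r = 0.322 for as2-1 minus wild type with as1-1 minus AS2 overexpressing and 0.0751 for AS2 overexpressing minus wild type with as2-1 minus as1-1. With the AS2 overexpressing array as the reference, 96 genes differed the same way in both mutants, 71 higher and 25 lower, and 29 of these were shared with the 124 counted against wild type.

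**Figure D1:**
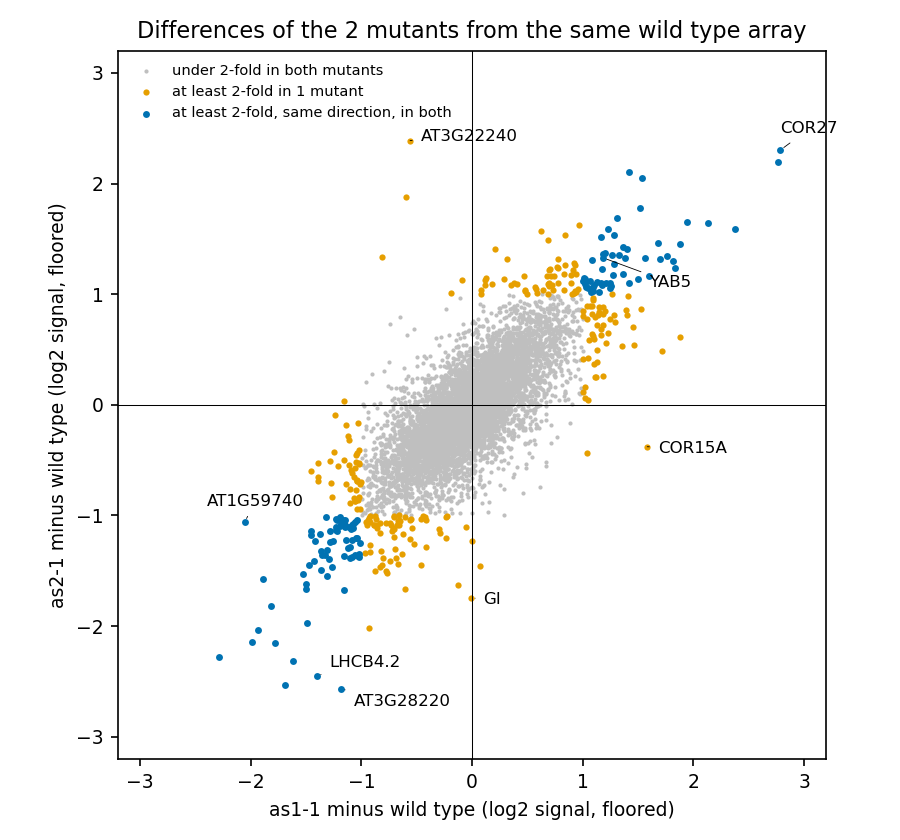
Floored log2 differences of as1-1 (x axis) and as2-1 (y axis) from the same wild type array, 1 point per gene, lower bounds included. The 124 genes at least 2-fold apart in the same direction in both mutants (blue) lie in the upper right (55) and lower left (69), with GI, COR15A and AT3G22240 among genes that reached 2-fold in 1 mutant (orange).

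The mutants were also set directly against each other. COR15A was higher in as1-1 than in as2-1, at 1195 against 306.5 (log2 difference 1.96), and so was GI, at 605 against 181.8 (1.73). AT3G22240 was lower in as1-1, at 80.32 against 620.1 in as2-1, and AT1G04770 at 33.38, under the floor, against 238.4. The auxin response list had a median log2 difference of 0.411 between as1-1 and as2-1, at percentile 99.3 of random lists, with WES1, a GH3 family gene, at 0.591, IAA29, below the floor in as2-1, at 0.853 or more, IAA30 at 0.23 and GH3.3, also of the GH3 family, on the other side at -0.168. In all 55 of 7538 genes differed at least 2-fold, 32 higher and 23 lower in as1-1, and 6 were lower bounds. The count was 20 with the floor at the 60th percentile and 164 with it at the 25th.

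Gain of AS2 was compared with wild type. YAB5 was among the genes lower in the AS2 overexpressing array, with a signal of 4.98, below the floor, and at least 3.53-fold lower than in wild type. MSRB6, a methionine sulfoxide reductase gene, was 4.67-fold lower, BCAT4, an aminotransferase gene of methionine chain elongation in glucosinolate synthesis, 3.12-fold lower (2201 to 706.3), and the metallothionein gene MT1C 2.87-fold lower (1135 to 395.8). COR27 was 6.94-fold higher, AT4G33980 5.14-fold higher and AT1G07050 4.08-fold higher, as on both mutant arrays. AT5G55450 was 3.3-fold higher, AT1G30820, a CTP synthase gene, 2.91-fold higher and EXLB1, an expansin-like gene, 2.81-fold higher.

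The remaining genes higher in the AS2 overexpressing array were AT4G32340 (2.66-fold), scpl35 (2.66-fold), AT1G61170 (2.59-fold), ATRER1C1 (2.53-fold), AT2G33170 (2.52-fold) and AT3G18510 (2.51-fold). The remaining genes lower there were AT3G13980 (3.62-fold), AT3G53980 (3.58-fold), AT4G27300 (3.28-fold), AT2G15280 (2.96-fold), AT5G15780 (2.86-fold), AT3G09860 (2.85-fold), AT5G05960 (2.84-fold), AT5G13770 (2.75-fold) and AT3G05900 (2.74-fold). PHV, an HD-ZIP III gene of the adaxial leaf side and the 1 named member of its list, had a log2 difference of 0.655, and the cytokinin response gene RR16 one of 0.894, both under 2-fold. The auxin response list had a median of -0.22. Of 7748 genes, 148 differed at least 2-fold, 55 higher and 93 lower, and 40 were lower bounds. Centring on all probe sets, which shifted the median difference of the genes above the floor on all arrays by 0.117, turned the balance to 90 higher and 62 lower, and loess gave 70 higher and 73 lower. The count was 542, 162 higher and 380 lower, with the floor at the 25th percentile and 43 with it at the 60th, where EXLB1, AT3G18510, MSRB6, AT3G53980, AT4G27300, AT2G15280, AT5G15780, AT3G09860, AT5G05960, AT3G05900 and YAB5 fell under 2-fold and AT1G61170 and AT2G33170 lay below the floor on both arrays.

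Gain and loss of AS2 were compared directly. YAB5 was at least 8.87-fold lower in the AS2 overexpressing array than in as2-1, and AT5G15780 was 7.23-fold lower, at 45.64 against 330. Both were higher in as2-1 and lower in the AS2 overexpressing array than in wild type, and they were the only 2 genes called that way in the main setting. With the floor at the 60th percentile neither was called lower in the AS2 overexpressing array and 0 genes were called that way, since their wild type signals then lay close to the floor. YAB5 was also higher in as1-1, while AT5G15780 had a signal of 74.43 there against 130.7 in wild type. BCAT4 stood at 706.3 in the AS2 overexpressing array against 2818 in as2-1 and AT3G22240 at 77.66 against 620.1, while GI stood at 653 against 181.8.

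Independent lists would give 1.41 genes higher in as2-1 and lower in the AS2 overexpressing array. Simulated unchanged arrays, whose spread came from the closest pair and may be too low, gave 0. The reverse pattern, lower in as2-1 and higher in the AS2 overexpressing array, held for 0 genes against 0.993 for independent lists, but with no floor for 153 against 63 of the first kind. Calls in the same direction were more frequent, with 24 genes higher and 31 lower on both arrays against 0.835 and 1.68 for independent lists and 0.09 and 7.08 in simulated arrays. The differences of as2-1 and of the AS2 overexpressing array from wild type had r = 0.478 (rho 0.464) and a covariance of 0.0783 across genes, beside simulated values of 0.5 and 0.037, and part of this may come from the shared wild type array. Between the 2 lines themselves, without wild type, 212 of 7595 genes differed at least 2-fold, 79 higher and 133 lower in the AS2 overexpressing array, with 26 lower bounds. That count was 100 with the floor at the 60th percentile and 510, 257 higher and 253 lower, with it at the 25th.

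**Figure D2:**
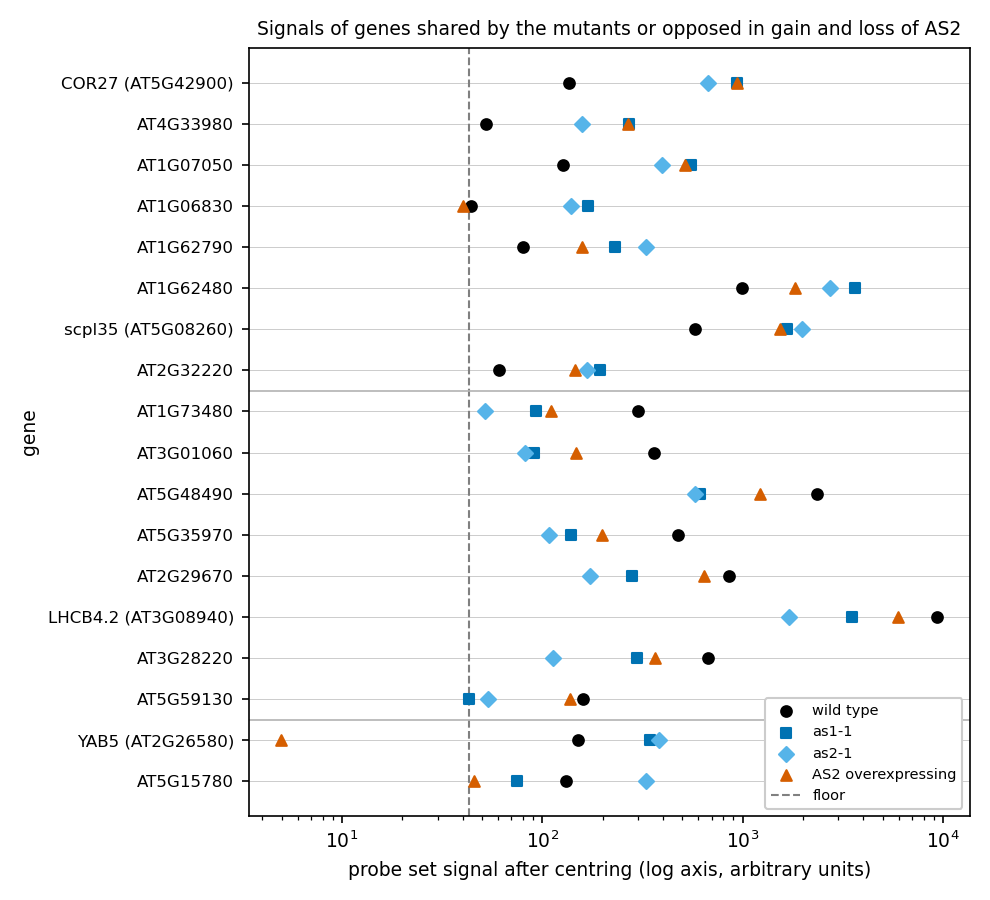
Scaled probe set signal (log axis, arbitrary units) on each of the 4 arrays, 1 marker per array, for the 8 genes higher in both mutants (top), the 8 lower in both (middle) and the 2 called in opposite directions in as2-1 and in the AS2 overexpressing array (bottom). The dashed line is the floor of 42.9, and YAB5 lies at 4.98 in the AS2 overexpressing array and at 344.4 and 380.2 in the mutants.

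The 4 arrays were also parted in every way to see on which genes they separated. The mutants together stood at least 2-fold from both other arrays on 29 genes, 16 higher and 13 lower, among them YAB5, the expansin gene EXPA20 (151.9 and 129.3 in as1-1 and as2-1, 51.5 in wild type and 50.62 in the AS2 overexpressing array) and GH9B8, a glycosyl hydrolase family gene (176 and 176.7 against 66.77 and 62.92). Lower in both mutants than on both other arrays were AT5G16030 (544.6 and 553.4 against 1510 and 1283), AT3G49160 (39.86 and 43.28, around the floor, against 210 and 173.4) and AT5G57345 (124 and 111.1 against 351.9 and 298.6). EXPA20 and GH9B8 were picked out after their values were seen. The other ways of pairing the arrays separated 1 gene each. Wild type stood at least 2-fold from all 3 others on 37 genes, 20 higher and 17 lower, including COR27, AT4G33980, AT1G07050, scpl35 and AT5G13770. The corresponding numbers were 6 for as1-1, 15 for as2-1 and 24 for the AS2 overexpressing array, of which 19 were lower there. With the floor at the 60th percentile the mutant pair stood apart on 13 genes and wild type on 12.

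**Figure D3:**
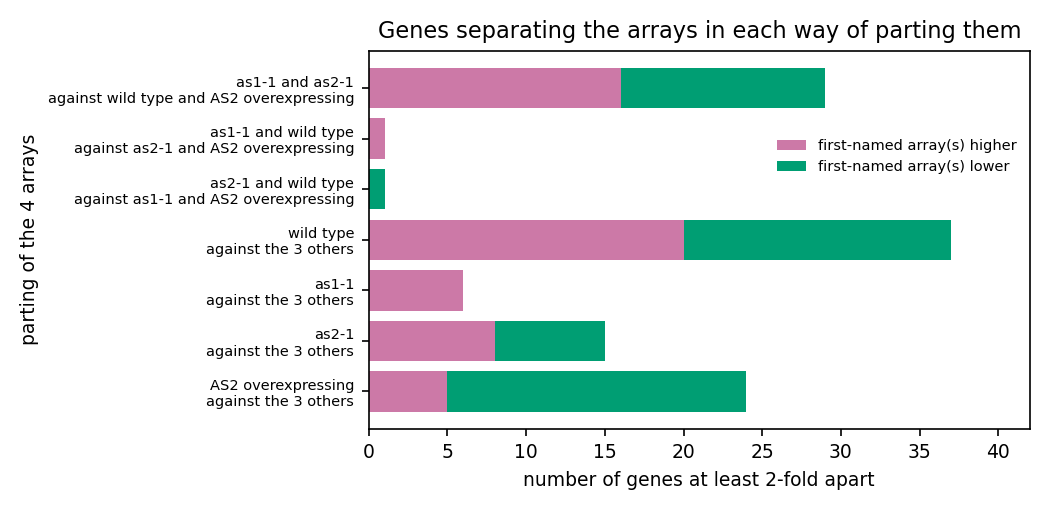
Number of genes (x axis) at least 2-fold apart for each way of parting the 4 arrays (y axis), split by whether the first-named array or arrays were higher or lower. Wild type against the 3 others separated 37 genes and the mutant pair against the other pair 29, while the other pairings separated 1 gene each.

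The remaining fixed lists held few named genes. In the abaxial list YAB3 accompanied YAB5 and stayed under 2-fold on every array, at 433.6 in wild type, 362.4 in as1-1, 430.1 in as2-1 and 400.7 in the AS2 overexpressing array. No named root, trichome or stomatal lineage marker was called against wild type. The stomatal lineage genes SPCH (217.6, 190, 214.7 and 191.9 in the same order) and FMA (91.66, 63.13, 76.56 and 81.01) were measured, and MUTE lay below the floor on every array. The root genes EXPA7 and EXPA18, the trichome gene TRY, the meristem and boundary genes CLV3 and LAS, and the LBD family genes LBD16 and LBD29 lay below the floor on all 4 arrays. The cytokinin response gene ARR15 and the lignin synthesis gene HCT did not reach 2-fold from wild type. The small RNA pathway gene AGO7 lay below the floor in wild type and at 81.21 in as2-1, a log2 difference of 0.921 or more, and the defensin gene PDF1.2 lay above the floor in the AS2 overexpressing array alone, at 47.77. UF3GT, of the flavonoid list, lay above the floor in as2-1 alone, at 70.62. The other 11 lists, among them class I and class II KNOX, gibberellin metabolism, mitotic cell cycle, epidermis and salicylate defence, had no named member and were not analysed here.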

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

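The tests of the ways to pair the arrays, of GI, of plastid-named genes, of the floor for the wild type pattern and of the floor for called genes were chosen only after the results were seen.

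Genes lower in a mutant can mark a segment of another accession's genome carried around the mutated locus, where probes match less well. The 111 named genes lower in as1-1 were not concentrated within 5 Mb of the AS1 locus. Their share there was 0.408 times that of all measured genes (95% exact binomial interval 0.112 to 1.01). The same window gave 1.32 in as2-1. This argues against such a segment as the source of these named genes. Another 119 probe sets lower in as1-1, with no gene or several listed, were not placed. The intervals here treat genes as independent, which neighbouring genes may not be. For as2-1 the share within 5 Mb of the AS2 locus was 1.56 times that of all genes (0.98 to 2.32), and the same window gave 1.34 in as1-1. The interval covers both no excess and a clear one, so a segment around AS2 stays open for part of the 20 genes there. Loss of AS1 or AS2 function remains open for both and was not tested beyond 1 array each.

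The mutants together stood apart from wild type and the AS2 overexpressing line on 29 genes. Scaling of the arrays is argued against, since quantile normalization gave 28 such genes and loess 27. Values near the floor stay open. Raising the floor to the 60th percentile shrinks the fold of any gene with 1 array below it. It kept 0.675 times as large a share of these genes as of all genes. That lies within the 0.437 to 0.71 found for the called genes of the 5 comparisons. Only 3 ways exist to part 4 arrays into pairs, too few for a share under 0.05, and 1 of them, the real one, gave as many genes, with 1 gene as the highest of the others. A common effect of losing AS1 or AS2 and handling shared by the mutant plants both stay open, and neither was tested.

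Wild type stood apart from all 3 others on 37 genes, among them COR27, lower in wild type than elsewhere, and scaling is argued against, with at least 35 such genes under quantile normalization and loess. Values near the floor stay open here too, since 12 genes were found with the floor at the 60th percentile, 0.488 times as large a share as of all genes and within the same range. A different share of green leaf tissue in the wild type sample stays open, because the gene lists did not settle it. The 20 plastid-named nuclear genes went both ways between the AS2 overexpressing array and wild type (8 higher and 12 lower, median log2 difference -0.0979). The median of the plastid genome genes was lower than in wild type on all 3 arrays. In as2-1 it depended on scaling, at -0.158 in the main setting and -0.0227 under quantile normalization. A harvest at another time of day could not be decided. The clock gene GI lay near its wild type level in as1-1 and the AS2 overexpressing array (log2 differences of -0.0103 and 0.0997). In as2-1 GI was lower (-1.74). COR27, 1 of the 37 genes and also linked to the clock, was higher than in wild type on all 3 arrays. GI and COR27 are single genes, too few to decide it. The rest of the 37 genes were not sorted by links to the clock or to light, so others may belong with COR27. Variation of the single wild type sample may therefore contribute to every comparison against it, and no biological explanation was tested.

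Outside the named genes, probe sets with no gene or several genes listed also carried differences of at least 2-fold from wild type, 230 in as1-1, 266 in as2-1 and 176 in the AS2 overexpressing array, of 9233 probe sets. Probe set 256766_at lay below the floor in wild type and at 1163 in as2-1, and 257985_at had 109.4 in wild type against 1447, 1919 and 1086 in as1-1, as2-1 and the AS2 overexpressing array. Probe set 258239_at had 4003 in wild type against 569.1, 118.2 and 1128, and 251497_at had 574.5 in wild type and 57.64 in as2-1.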

How the results depend on the processing

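Counting every probe set and using the AS2 overexpressing array as reference were tests chosen only after the data were seen. No paired analysis was possible because each genotype had 1 array. Counts are given in the order as1-1, as2-1 and AS2 overexpressing against wild type, as1-1 against as2-1, AS2 overexpressing against as2-1, genes shared by the mutants, and genes opposed in as2-1 and the AS2 overexpressing line. They were 222, 254, 148, 55, 212, 124 and 2 in the main setting. With the floor at the 25th percentile they were 660, 729, 542, 164, 510, 413 and 6, with it at the 60th 97, 116, 43, 20, 100, 56 and 0, and with no floor 3177, 3259, 2724, 2508, 2925, 1816 and 216. A size rule of 1.5-fold gave 1224, 1265, 932, 447, 1071, 677 and 27, and one of 3-fold 23, 32, 12, 7, 40, 12 and 0. Counting every probe set gave 454, 522, 328, 124, 470, 251 and 8, by construction from more items. Of the opposed genes, those lower in as2-1 and higher in the AS2 overexpressing line were 0 in the main setting, 6 of the 27 at 1.5-fold, 2 of the 8 over every probe set and 153 of the 216 with no floor. Under the other centrings, quantile normalization, loess and the probe set rules, each count stayed within 1.5-fold. Without a floor the correlation of the mutants' differences was 0.576 and that of the pair without a shared array 0.114, where genes near background enter; the cause was not tested. Of 781 values of named genes under alternatives, 749 stayed at least 2-fold, 32 did not, 31 of them with the floor at the 60th percentile, and 0 reversed, while 2 more calls were lost at that floor because both arrays lay below it. Several alternatives could not lose a call. Each named gene had 1 probe set, not of the s or x type, and lowering or removing the floor cannot shrink a difference. The 749 values are therefore partly fixed by construction. With the floor at the 60th percentile, 54 of 85 values stayed at least 2-fold. The list medians for auxin response and reference genes moved by less than 1.5-fold in each alternative that could be computed, and with the floor at the 60th percentile too few auxin genes were left for a value. That limit is wider than each of these medians, so it says little of their stability. In the AS2 overexpressing array the auxin median was -0.133 with centring on all probe sets and -0.343 with the floor at the 25th percentile. The reference median in as1-1 was -0.00784 with the floor at the 60th. Signal over background limits genes near 42.9, where a difference is a bound or noise.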

Other observations

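The lists described here were drawn up only after values had been seen, so their results describe the arrays and are not independent evidence.

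A list of 22 genes of glucosinolate synthesis and transport, made after BCAT4 was seen, had 5 members named on the array. BCAT4 itself was 1 of these 5 and enters the medians and percentiles below. Their median log2 difference was 0.413 in as1-1 and 0.768 in as2-1 from wild type and -0.535 in the AS2 overexpressing array, at percentiles 98.6, 100 and 0.085 of random lists, and it kept its sign under every scaling tried. Between the AS2 overexpressing array and as2-1 the median was -1.25, with 4 of the 5 genes, BCAT4 among them, at least 2-fold lower. Against wild type, BCAT4 was the only member called in the AS2 overexpressing array. AT2G31790, a glucosyltransferase gene, had signals of 398.6, 554, 815.6 and 258.5 in wild type, as1-1, as2-1 and the AS2 overexpressing array. UGT74B1 had 462, 785.6, 735.4 and 319, and the transporter gene GTR1 125.4, 136.7, 276.9 and 116.3. GTR2 was higher in the AS2 overexpressing array than in wild type, at 366.3 against 277.

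Nuclear genes whose names or synonyms carry a plastid or photosynthesis word, 20 in all, had median log2 differences from wild type of -0.48 in as1-1 and -0.485 in as2-1, each at percentile 0.02 of random lists. These percentiles belong to the main setting. The medians were -0.254 and -0.353 under quantile normalization and -0.294 and -0.421 under loess, so their size depended on scaling. In the AS2 overexpressing array the median was -0.0979, and it was 0.0195 with centring on all probe sets. PORB, an enzyme gene of chlorophyll synthesis, had signals of 6081, 3933, 2701 and 6365 in wild type, as1-1, as2-1 and the AS2 overexpressing array, and PSBY had 7244, 3998, 3400 and 5419. In contrast CHL stood at 1150, 1640, 1613 and 1425. The 69 genes of the plastid genome had medians of -0.235, -0.158 and -0.28 in as1-1, as2-1 and the AS2 overexpressing array, of -0.095, -0.0227 and -0.202 under quantile normalization and of -0.0889, -0.0415 and -0.244 under loess.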
